A study of Arabidopsis thaliana with 12 samples.

How the data were processed

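RNA was taken from whole Arabidopsis thaliana seedlings, control or exposed to volatile compounds of Tolypocladium inflatum GT22, at 3, 24 and 48 h. Labels give 2 libraries per group and 12 in all. Nothing in them says that the libraries came from separate cultures, so p-values may measure technical spread only. Trimmomatic 3.6 and TopHat were used and the build was TAIR10, per the submitters' processing notes. The 3 deposited tables have the column layout of a Cuffdiff gene test, per the file headers. The tool that wrote them is not given in the sources used here. The FPKM values were computed by the authors, with 1 value per gene and group. The deposited p-values and q-values and the deposited test statistic, a score, come from the authors' own comparison of volatile against control. The time of each table is known only from its name, and the labels tie no library to a table.

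Because the tables hold no value per library, the planned limma model, its gene set tests and every alternative that needs libraries were not run. Calls at a single time are the authors' own, at a q-value under 0.05. Recomputed by the Benjamini-Hochberg method over tested rows, the q-values differed from the deposited ones by no more than rounding. The deposited log2 fold change was not used, because 446, 520 and 472 of its cells at 3, 24 and 48 h could not be read. It was computed again from the FPKM values with no pseudocount, and no fold is given against a value of 0. Tables held 26797, 26605 and 26664 rows, of which 19480, 19326 and 19415 were tested. Rows without a gene name were 1.24%, 1.29% and 1.28%. Rows that merge several genes numbered 894, 1054 and 1018 and stayed out of the gene lists. Where a gene had several rows, a tested row was preferred, then the most abundant. No other column of per-sample values was present or used.

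Some zeros can be failed estimates, since AT3G08520, a ribosomal protein gene, was listed at 0 in the 24 h controls and at 4754 FPKM under the volatiles. A gene is therefore only said to be listed at 0. The implied error was the log2 fold change divided by the deposited statistic, with a median of 0.29, 0.31 and 0.31 at 3, 24 and 48 h. It assumes that the statistic is a fold change over its error, which no header states. For rows such as CYP79B2 and KIN2 at 3 h, the deposited p-value was smaller than this reading gives. The implied error can therefore be larger than the error behind the deposited p-value. The 3 tables were built separately, so levels at different times are not compared.

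The 29 gene lists hold 599 loci, fixed before the data were examined, and 598 were kept after matching symbols to the reference annotation (TAIR10.1) without regard to punctuation, an AT prefix or a final 1. List medians were compared with 10000 random lists matched in 20 bins of mean expression, for lists with at least 3 measured members. The 99% range was chosen after seeing the data, in place of the planned gene set test. Simulated genes at 3 h were independent, with fold changes shuffled over all genes. Of 1000 unchanged lists of 20 members 1.0% fell outside this range, and 98.5% of lists shifted by 0.2 at every member. The shuffle removes any link of fold change to expression, so the 1.0% followed from the setting. Coordinates are those of the tables, counted from 1. Every single-gene row that could be compared overlapped its gene in TAIR10.1, and about 14.0% had the same bounds.

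Tests between times used rows with a mean of at least 1 FPKM in each table. They dropped rows with a p-value of at least 0.05 although the statistic, read as a normal deviate, gave one under 0.05. These disagreeing rows numbered 16, 14 and 21 of those tested at 3, 24 and 48 h. Rows with a p-value smaller than the statistic gave, such as FER1 at 3 h, were kept. The filter and the drop were chosen after an unfiltered run. It passed 0, 5 and 1 rows for 3 against 24 h, 3 against 48 h and 24 against 48 h. A test over all 3 times used the weighted sum of squares of the fold changes. On simulated data, with noise drawn from the implied errors, it recovered 0.50%, 82.0% and 92.0% of 200 genes that differed by 1, 2 and 3 log2 units.

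Named genes followed a rule whose form was fixed before the data were examined, with list calls and a test between times chosen afterwards. It takes per time the 8 highest and 8 lowest fold changes among called genes with a mean of at least 5 FPKM, up to 4 members of each list outside its random range by smallest q-value, up to 6 genes per direction called at all 3 times, the 6 smallest p-values of the test between times, and a panel of 16 genes. Its condition on single libraries could not be applied. Ties in q-value were broken by p-value and then by the size of the statistic. CYP82C4, MGD3, CYP81D8, AKR4C9, LBD41 and SAD6 are among those named as list members. DRM2, JAZ9, VSP1 and AIG1 at 24 h, HRA1 at 48 h, NRT2.1, and genes named for being listed at 0 or chloroplast-encoded were chosen after their values were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were a stricter and a looser q-value, a fold-change floor, other filters, quantile normalization, pseudocounts of 1 and 0.1 FPKM, and other summaries and random lists.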

Results

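The data describe mRNA levels in whole Arabidopsis thaliana seedlings exposed to volatile compounds of the fungus Tolypocladium inflatum strain GT22, and in control seedlings. Seedlings were sampled at 3, 24 and 48 h, with 2 libraries per group, 6 groups and 12 libraries in all. The series was made to find which molecular responses the volatiles trigger. The values are FPKM, fragments scaled by transcript length and by the number mapped, and the authors' deposited tables give 1 value per gene and group, with a statistic, a p-value and a q-value for volatile against control. The spread between the 2 libraries of a group therefore cannot be seen, sequencing depth is unknown, and no SD is given. The error printed beside a log2 fold change is the one implied by the authors' deposited table, the fold change divided by its statistic. It can be larger than the error behind the deposited p-value. "Rose" and "fell" are used of genes with a q-value under 0.05 in that table.

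At 3 h, genes induced by low oxygen and genes of aliphatic glucosinolate synthesis were among those that rose, and genes of phosphate starvation and a ferritin gene, FER1, were among those that fell. PCO1 (AT5G15120, TAIR10 chromosome 5, 4898642 to 4900581), a plant cysteine oxidase induced by low oxygen, went from 1.81 to 8.42 FPKM, a log2 fold change of 2.22 with an implied error of 0.44. HRA1 (AT3G10040, chromosome 3, 3096415 to 3098071), a transcription factor that attenuates the hypoxia response, went from 1.73 to 4.82 FPKM. HB1, a non-symbiotic haemoglobin, went from 5.71 to 12.3 FPKM, and PDC1 (AT4G33070, chromosome 4, 15952289 to 15954771), a pyruvate decarboxylase of fermentation, from 5.63 to 10.7 FPKM. CYP79F1 and BCAT4, enzymes of aliphatic glucosinolate synthesis, rose with log2 fold changes of 1.46 and 0.73. FRO2, the root ferric reductase, rose with a log2 fold change of 0.75, and CYP82C4, another gene of the iron deficiency response, from 2.17 to 5.13 FPKM.

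Genes that fell at 3 h included CYP81D8, a cytochrome P450, with a log2 fold change of -1.93 and an implied error of 0.42. The phosphate starvation genes PPsPase1, a pyrophosphatase, and MGD3, a galactolipid synthase, fell with log2 fold changes of -1.43 and -1.17. FER1, an iron-storing ferritin, went from 108.0 to 66.0 FPKM, AT2G43620 (chromosome 2, 18093770 to 18095025) from 39.1 to 16.0 FPKM, and BCB from 20.7 to 9.93 FPKM. In all, 22 of 19480 tested rows had a q-value under 0.05 in the authors' deposited table at 3 h, 11 higher and 11 lower under the volatiles. All 22 had the smallest p-value the table holds, 5e-05, which gives a q-value of 0.0443. Without rows at larger p-values, about 20 rows at 5e-05 were needed for any call. No row with a larger p-value was called at 3 h. At 48 h BCAT4, with a p-value of 1e-04 in the authors' deposited table, was called at a q-value of 0.0396.

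Gene lists fixed before the data were examined were described by the median log2 fold change of their members, set against 10000 random lists matched on expression. This describes the tables and is not a test on replicates. Members of a list are co-regulated and drawn genes are not, so the random range is too narrow for a significance claim: 12, 10 and 13 of 29 lists lay outside the central 99% at 3, 24 and 48 h, where independent genes would give 0.87 in all 87. At 3 h the hypoxia list had a median of 0.82 over 14 members, against a random range of -0.20 to 0.14, and a mean of 0.51. Of the 14 members, 10 lay above 0 and 4 below. Among all genes tested 4 members rose, and 9 when adjusted over the list alone. The aliphatic glucosinolate list had a median of 0.50, with 18 of 18 members above 0, 2 risen among all genes tested and 9 adjusted over the list alone. The ferritin list had a median of -0.71 over only 3 members, of which FER1 alone fell by either adjustment, and of -0.34 when rows that merge several genes were included. Sugar starvation genes had a median of -0.28, with 0 members fallen among all genes tested and 3 adjusted over the list alone, and phosphate starvation genes a median of -0.24, with 2 fallen among all genes tested and 3 adjusted over the list alone. Camalexin, indole glucosinolate and iron deficiency lists had medians of 0.16, 0.13 and 0.11, with 0, 0 and 2 members risen among all genes tested and 0, 0 and 4 adjusted over the list alone. Detoxification, dehydration, sulfur and heat shock lists had medians of -0.11, -0.17, -0.14 and -0.16. Of 23 dehydration genes, 0 changed among all genes tested, and 2 rose and 1 fell adjusted over the list alone. With means in place of medians, a setting chosen after seeing the data, the camalexin, indole glucosinolate and dehydration lists lay inside the random range at 3 h, at percentiles 75.8, 98.95 and 19.9.

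**Figure D1:**
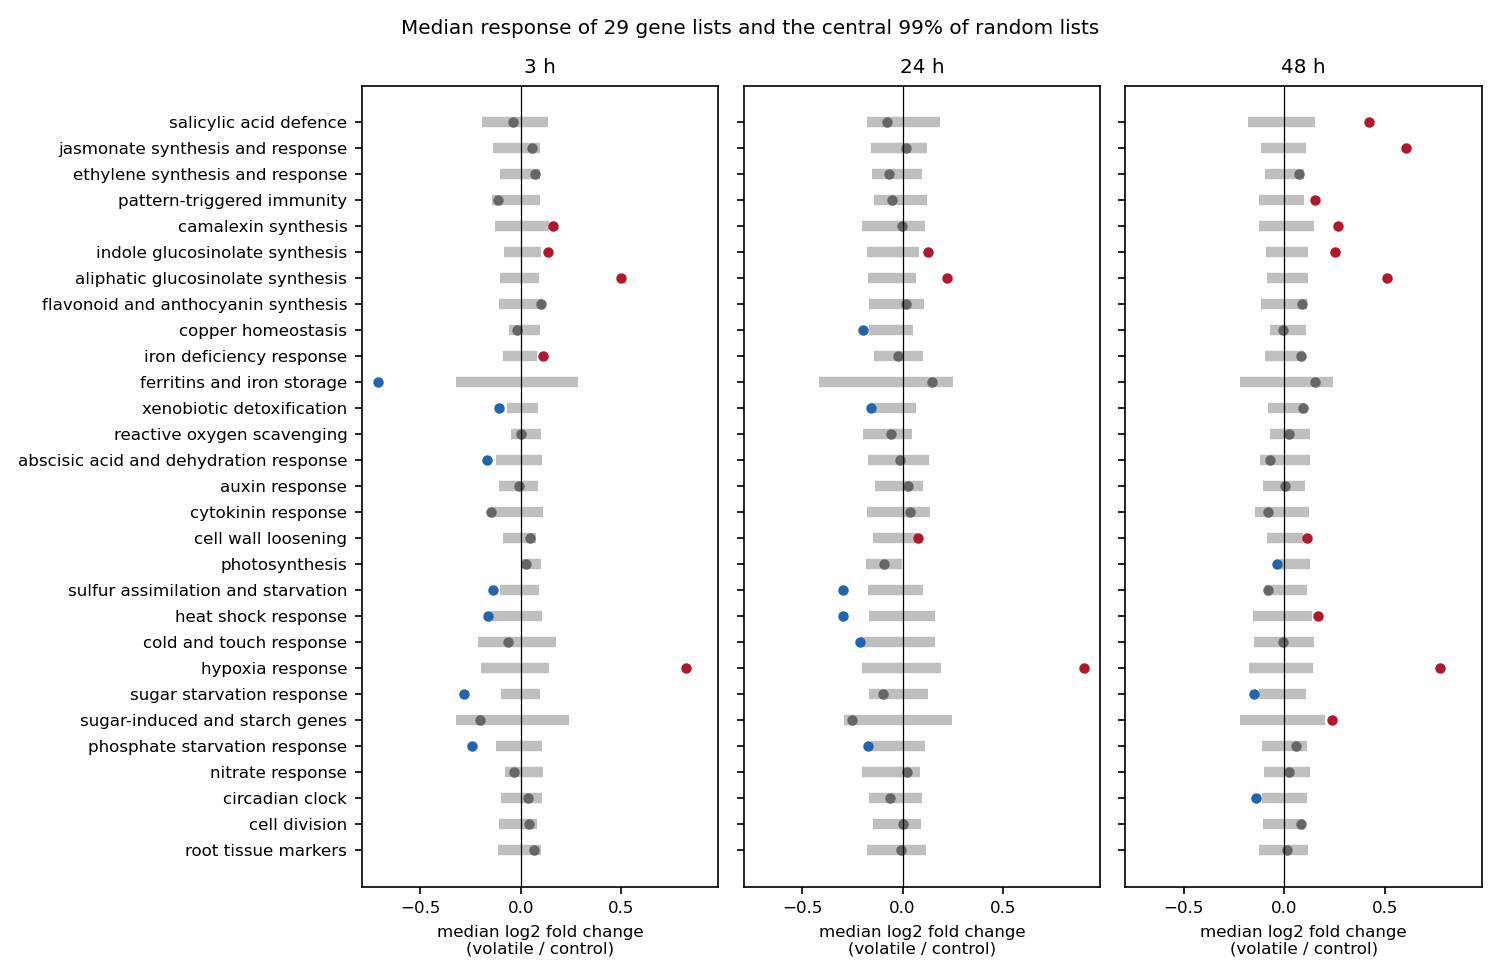
Median log2 fold change, volatile over control, of 29 gene lists at 3, 24 and 48 h (points) and the central 99% of random lists matched on expression (grey bars). Red and blue points lie above and below the bar, and the hypoxia list lies far above it at each time, at 0.82, 0.90 and 0.77.

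At 24 h fewer genes rose than fell. PCO1 and PDC1 rose again, with log2 fold changes of 2.31 and 1.11, and HRA1 rose 2.82-fold. The highest rise was that of AT3G04184, from 0.93 to 27.4 FPKM, followed by a row that merges AT3G13403 and AT3G13404, with a log2 fold change of 3.78. Since that row holds both genes, its change cannot be given to either one. Among genes that fell, AT2G16005 went from 14.8 to 2.51 FPKM and AT1G66100 from 27.0 to 8.30 FPKM. AKR4C9, an aldo-keto reductase, fell with a log2 fold change of -1.59, TIP2;3, a vacuolar membrane aquaporin, with -1.19, and GPT2, a plastid glucose phosphate transporter, with -0.92. DRM2, a dormancy-associated gene, went from 80.6 to 42.6 FPKM. The authors' deposited table called 24 of 19326 tested rows, 8 higher and 16 lower, all at a q-value of 0.0403.

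The hypoxia list had a median of 0.90 at 24 h over 12 members, of which 3 rose among all genes tested and 8 adjusted over the list alone. The aliphatic glucosinolate median was 0.22, with 0 members risen by either adjustment. Copper homeostasis genes, which bear on the copper stress named in the title of the series, had a median of -0.19, and lay inside the random range at 3 and 48 h, with medians of -0.02 and -0.01. At 24 h, none of their 25 measured members fell among all genes tested, 1 fell adjusted over the list alone, and 6 were lower at an unadjusted p-value under 0.05 in the authors' deposited table. Among these, COPT1, a copper transporter, stood at 170.2 and 111.5 FPKM, MT2A, a metallothionein, at 502.5 and 356.1 FPKM, and CCH, a copper chaperone, at 688.6 and 487.5 FPKM, control first. The seedlings' copper supply is not stated in the sources used here. Sulfur and heat shock lists both had medians of -0.30, with means of -0.37 and -0.60. No sulfur gene fell by either adjustment, and 4 heat shock genes fell adjusted over the list alone. Phosphate, cold and touch, and detoxification lists had medians of -0.17, -0.21 and -0.16, and cell wall loosening and indole glucosinolate lists medians of 0.08 and 0.13, although 1 cell wall gene fell and 0 rose adjusted over the list alone. The indole glucosinolate, cell wall, cold and touch, and phosphate lists lay inside the random range with means, and also with random lists not matched on expression. The detoxification and the cold and touch lists did so with no filter and with quantile normalization, detoxification also with a filter on mean FPKM, and phosphate with a pseudocount of 1.

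**Figure D2:**
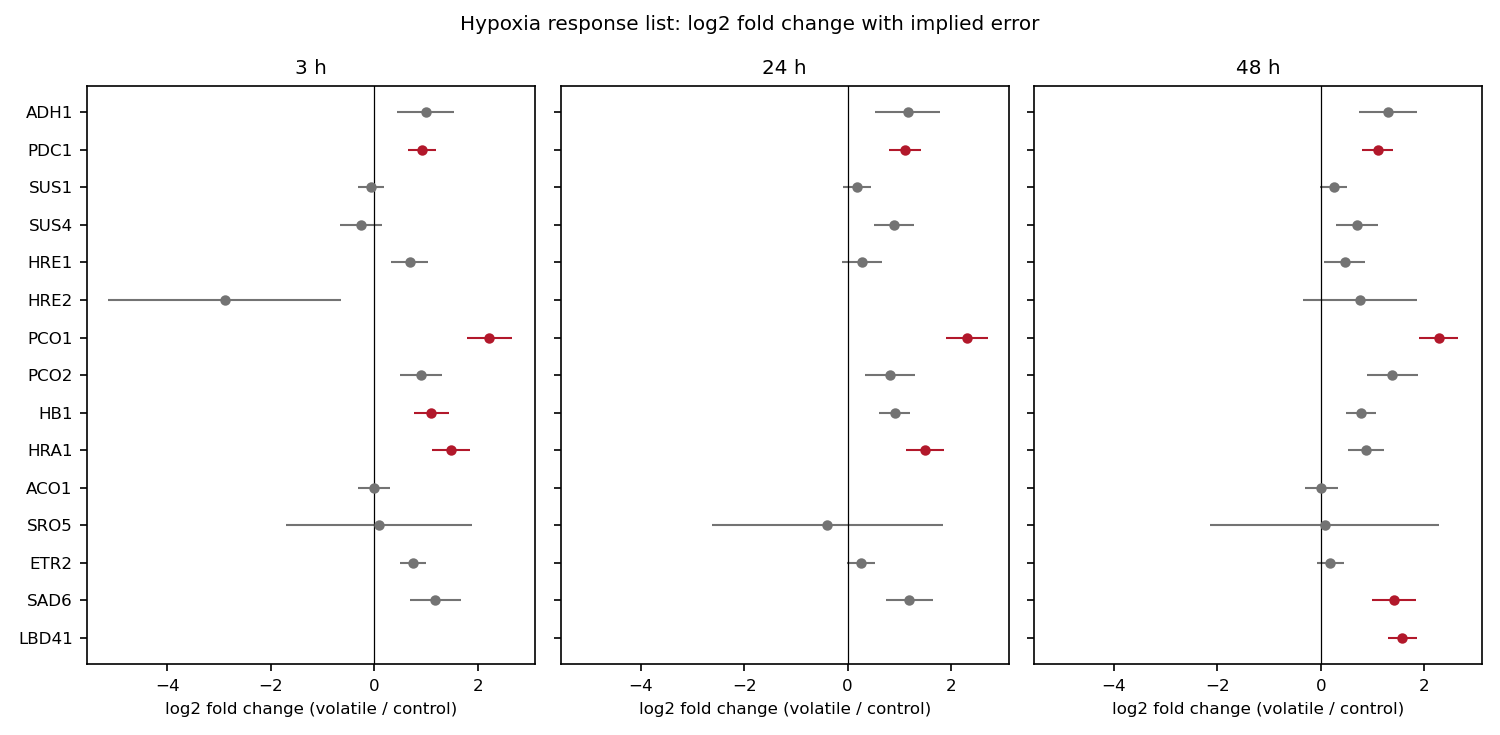
Log2 fold change, volatile over control, of the measured members of the hypoxia list at 3, 24 and 48 h. Bars show 1 implied error on each side, and red points have a q-value under 0.05 in the authors' deposited table. PCO1 lies at 2.22, 2.31 and 2.27.

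At 48 h more genes rose than fell, and genes of jasmonate synthesis, aliphatic glucosinolates and camalexin were among those that rose. LOX2 (AT3G45140, chromosome 3, 16525410 to 16529352), a lipoxygenase of jasmonate synthesis, rose from 27.6 to 90.4 FPKM, a log2 fold change of 1.71 with an implied error of 0.26. AOS and AOC1, the following enzymes of that pathway, rose with log2 fold changes of 0.92 and 0.86, and JAZ9, a repressor of jasmonate signalling, with 0.91. PAD3 and GSTF6, which act in camalexin synthesis, went from 2.99 to 6.98 FPKM and from 53.4 to 135.3 FPKM. AIG1 (AT1G33960, chromosome 1, 12346232 to 12348513), a gene induced by avirulent bacteria, rose from 0.64 to 10.3 FPKM, FAMT, a farnesoic acid methyltransferase, with a log2 fold change of 3.99, and DIN11 from 1.90 to 11.6 FPKM. CYP79F1, FMOGS-OX1, FMOGS-OX3 and BCAT4 of aliphatic glucosinolate synthesis rose with log2 fold changes of 0.90, 0.97, 0.79 and 0.69. IRT1, the root iron transporter, rose from 21.5 to 40.4 FPKM, and NRT2.1, a nitrate transporter, from 7.27 to 14.0 FPKM. PCO1, LBD41 and SAD6 of the hypoxia list rose with log2 fold changes of 2.27, 1.57 and 1.41, and PDC1 rose from 6.12 to 13.1 FPKM.

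Genes that fell at 48 h included DTX3, a transporter of the MATE family, from 10.6 to 2.78 FPKM, DRM2 from 129.5 to 57.7 FPKM, GASA6 from 358.2 to 181.1 FPKM, and EXPA1, an expansin, from 258.0 to 145.7 FPKM. FRO6, a leaf ferric reductase, fell with a log2 fold change of -0.75. The authors' deposited table called 49 of 19415 tested rows, 42 higher and 7 lower. In that table, 536 rows had an unadjusted p-value under 0.05, 300 higher and 236 lower, against 573 at 24 h, and no test compared the number of changed genes between times. With the deposited statistic read as a normal deviate in place of the deposited p-value, a setting chosen after seeing the data, the counts at 3, 24 and 48 h were 9, 12 and 21, of which 4, 5 and 12 were also among the deposited calls.

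The jasmonate list had a median of 0.61 at 48 h, with 25 of 26 members above 0. Of these, 4 rose among all genes tested and 11 adjusted over the list alone. At 3 and 24 h its medians of 0.05 and 0.01 lay inside the random range, and at 24 h JAZ9 and VSP1 fell adjusted over the list alone, with 0 members fallen among all genes tested. At 48 h the salicylic acid list had a median of 0.42, which was 0.26 with a pseudocount of 1 and 0.28 with a filter on mean FPKM. It had 0 of 18 members risen among all genes tested and 2 adjusted over the list alone, and the pattern-triggered immunity list a median of 0.15 with 0 and 1. PR1, the usual marker of the salicylic acid response, was listed at 0 in both groups at 48 h. The jasmonate markers VSP2 and PDF1.2a stood at 0.83 and 2.15 FPKM and at 5.71 and 16.1 FPKM, control first, and neither passed the q-value threshold. The aliphatic glucosinolate list had a median of 0.51, with 4 of 19 members risen among all genes tested and 12 adjusted over the list alone. The camalexin and indole glucosinolate medians were 0.27 and 0.25. Of 16 indole glucosinolate genes 0 rose among all genes tested and 0 adjusted over the list alone. Of 14 camalexin genes 2 rose among all genes tested, and 2 rose and 1 fell adjusted over the list alone. The hypoxia median was 0.77, with 4 of 15 members risen among all genes tested and 9 adjusted over the list alone. Heat shock genes and sugar-induced genes had medians of 0.17 and 0.24. In these 2 lists 0 members rose among all genes tested, and 0 and 1 adjusted over the list alone. The circadian clock list had a median of -0.14, photosynthesis -0.04 and sugar starvation -0.15, with 0, 0 and 1 members fallen by either adjustment. The cell wall loosening median was 0.11 although its called member, EXPA1, fell. Photosynthesis lay inside the random range with quantile normalization, with unmatched random lists and with means, at percentiles 23.7, 15.7 and 2.18, and the clock list with a pseudocount of 1 and with means. With means the camalexin, cell wall, heat shock, sugar starvation and sugar-induced lists also lay inside it, and with no filter the heat shock and sugar starvation lists.

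**Figure D3:**
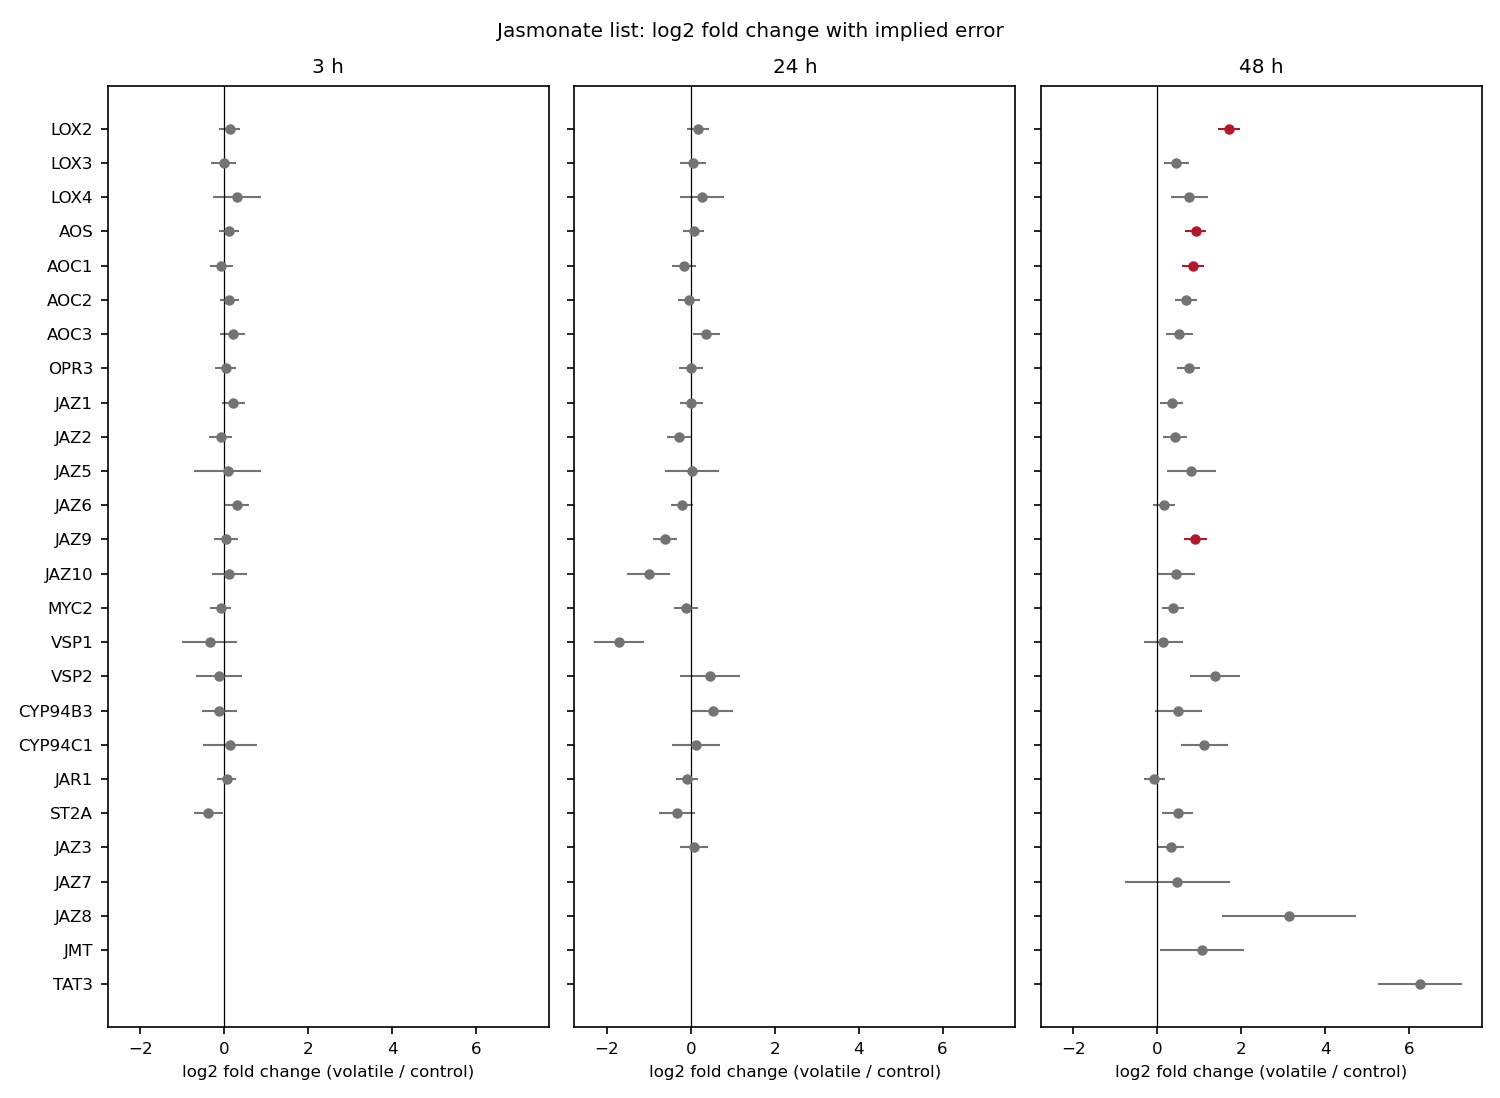
Log2 fold change, volatile over control, of the measured members of the jasmonate list at 3, 24 and 48 h. Bars show 1 implied error on each side, and red points have a q-value under 0.05 in the authors' deposited table. At 48 h 25 of 26 members lie above 0.

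PCO1 and PDC1 rose at all 3 times, and no gene fell at all 3. With the statistic read as a normal deviate, or with a log2 fold change of at least 1, PCO1 alone did so. HRA1 rose at 3 and 24 h and had a log2 fold change of 0.87 at 48 h with a q-value of 0.18 in the authors' deposited table. Among rows tested at both times, 3 rose at both 3 and 24 h, where independent lists would share 0.0045 (two-sided Fisher's exact test, adjusted p = 4.2e-08 over 12 overlaps). The overlap of genes that rose was 4 between 3 and 48 h, PCO1, PDC1, BCAT4 and CYP79F1, and 3 between 24 and 48 h. DRM2 fell at 24 and 48 h (adjusted p = 0.019 for this overlap of 1). Overlaps in opposite directions held no gene, apart from those of AT2G43620 and AT4G12490 alone. AT2G43620 fell at 3 h and rose at 48 h (adjusted p = 0.049 by the same test, for an overlap of 1). AT4G12490 fell at 24 h and rose at 48 h (adjusted p = 0.068 by the same test, for an overlap of 1). These p-values, like that for DRM2, concern the size of an overlap and do not test the gene itself. With 0.021, 0.035 and, for DRM2, 0.0062 genes expected, 1 shared gene alone sets them. Each time has its own controls. Across genes, fold changes correlated weakly between times, with Pearson's r of 0.11, 0.10 and 0.16 for 3 and 24 h, 3 and 48 h, and 24 and 48 h. Genes are not independent replicates.

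Whether a response differed between times was tested from the fold changes and their implied errors, by a normal test with Benjamini-Hochberg adjustment. This test, and its limit to rows with a mean of at least 1 FPKM, were chosen after the deposited values and an unfiltered run had been seen. AT2G43620 fell at 3 h and rose at 48 h, with log2 fold changes of -1.29 and 1.14, and its difference of 2.43 had a 95% interval of 1.64 to 3.22 (adjusted p = 3.0e-05). LOX2, GSTF6 and the AT3G13403 and AT3G13404 row also passed for 3 against 48 h, each at an adjusted p of 0.048, and all 3 were lost with no filter, with quantile normalization and with a pseudocount of 0.1, which left AT2G43620 alone. They passed again with no filter when rows whose statistic and p-value disagree were kept. AIG1 differed between 24 and 48 h, from -1.52 to 4.02, with an adjusted p of 3.8e-09, and AT4G12490 did not pass, at 0.12. Between 3 and 24 h 0 genes passed, and 47 of 16749 rows had an unadjusted p-value under 0.05. The counts were 74 of 16866 for 3 against 48 h and 71 of 16888 for 24 against 48 h. Uniform p-values would put a share of 0.05 of rows under that threshold, and all 3 counts were far lower. The test was therefore conservative in these data, and few passing genes do not show that responses were alike. Over all 3 times together 3 rows passed, AT2G43620, LOX2 and the merged row. AIG1 was untested at 3 h in the authors' deposited table and could not enter this test. At 24 h AIG1 stood at 2.30 and 0.80 FPKM, control first, with a q-value of 0.42 in that table. On simulated data for 3 against 48 h, noise was drawn from the same implied errors, so the simulation cannot show whether they match the data. The test found 7 of 200 genes that differed by 1 log2 unit, 150 of 200 at 2 and 186 of 200 at 3. With these errors, differences near 1 were mostly not detectable. Since the test was conservative here, the errors can be too large and the simulated recovery too low. A list or gene that stood out at 48 h and not earlier is therefore not shown to differ unless it is named here.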

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

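The tests between times in this part were chosen after the result was seen. AT2G43620 responded differently at 3 and 48 h, by 2.43 on the log2 scale (48 h minus 3 h). GSTF6 differed by 1.63, LOX2 by 1.58 and the row that merges AT3G13403 and AT3G13404 by 6.02 between the same times, and these 3 were lost with quantile normalization, with a pseudocount of 0.1 and with no filter on low values, unless rows whose statistic and p-value disagree were kept. AIG1 differed by 5.54 between 24 and 48 h. A row with no gene name, on chromosome 4 from 4980859 to 4983605, was called at 3 h in the authors' deposited table, listed at 0 in controls and at 1.05 FPKM under the volatiles. In TAIR10.1 the pseudogene AT4G08091 overlaps it.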

How the results depend on the processing

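No paired analysis was possible because the tables hold 1 value per group, and for the same reason leaving out libraries, the fits on 4 libraries, camera, fry, another count tool and a filter on untested rows were not run for gene calls. Settings other than the adjusted p under 0.01, the fold-change floor, quantile normalization, the pseudocount of 0.1 in the tests between times, and no filter were chosen after seeing the data. With an adjusted p under 0.01 the counts of changed genes were 0 at 3 h, 0 at 24 h and 0 at 48 h, and 0 genes were changed at all 3 times. The smallest p of 5e-05 fixes this, since it gives q-values of 0.0443, 0.0403 and 0.0221. A log2 fold change of at least 1 left 12 genes at 3 h, 17 at 24 h, 28 at 48 h and 1 at all 3 times (PCO1), by construction. The statistic as a normal deviate gave 9, 12 and 21 genes, and 1 at all 3 times, PCO1 and not PDC1. At 3 h PDC1 had a log2 fold change of 0.92 with an implied error of 0.28. Read as a normal deviate, this gives a larger p-value than the deposited 5e-05. Other rows differed in the same direction. At 3 h CYP79B2 had a log2 fold change of 0.23, an implied error of 0.23 and a deposited p-value of 0.16. For KIN2 at 3 h these were -0.48, 0.24 and 0.00415. HSP17.6A at 24 h went the other way, and such rows were counted only where the deposited p-value was at least 0.05. For CYP79B2 and KIN2 the implied error was therefore larger than the deposited p-value implies, and why was not tested. An unadjusted p under 0.05 gave 30 genes at all 3 times. For responses that differed between times, an adjusted p under 0.01 left 1 and one under 0.1 gave 6. For 3 against 24 h an adjusted p under 0.1 gave 1. For 3 against 48 h, an adjusted p under 0.01, no filter, quantile normalization and a pseudocount of 0.1 each left 1, AT2G43620, and the cause was not tested. With means in place of medians, 9 lists at 3 h, 6 at 24 h and 7 at 48 h lay outside the random range, against 12, 10 and 13 with medians. At 3 h means ended the calls of camalexin, indole glucosinolate and dehydration. At 48 h they ended those of camalexin, heat shock, sugar-induced genes, cell wall loosening, clock, photosynthesis and sugar starvation, and added ethylene. Unmatched random lists left 6 at 24 h, where both settings ended the calls of indole glucosinolate, cell wall loosening, cold and touch, and phosphate, and the cause was not tested. Of 432 fold changes of named genes recomputed with pseudocounts, 414 moved by less than 1 implied error, 18 by more and 0 reversed. Depth is unknown, and limits for low genes cannot be given.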

Other observations

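All tests in this part were chosen after the pattern they address was seen, and the bounds for root tissue, scaling, the clock, a single library and short genes also after values that bear on them. The second hypoxia list and its bounds were written before its own values were seen. Fewer rows than the 5% expected of uniform p-values had a p-value under 0.05 in the authors' deposited tables, 2.24% at 3 h, 2.96% at 24 h and 2.76% at 48 h.

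The hypoxia list was higher at all 3 times. A larger share of root tissue would raise root markers, but their highest median was 0.064 (95% bootstrap interval up to 0.25 at 3 h). The median of all tested genes was -0.022 at its farthest from 0. FPKM are already scaled by the number mapped, so a median near 0 may come from the processing. Nothing is concluded from it about scaling between the groups, and a factor common to all genes would also move the random lists. A low-oxygen response, which no label names, may account for the higher hypoxia list. However, a second list of 29 hypoxia genes, written without genes already called, had medians of 0.05, 0.01 and 0.09. These lay at percentiles 94.9, 71.7 and 99.4 of random lists, with 0 members risen at each time adjusted over the list alone. The value of 71.7 at 24 h met the bound written beforehand as speaking against low oxygen; it is left open here because the interval of that median spans percentiles 0.22 to 100 and called genes had been left out, a reading made after the value was seen.

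The jasmonate list was higher at 48 h. A harvest at another time of day may contribute: the median absolute change of 19 clock genes lay at percentile 98.1 of random lists, though its interval spans percentiles 22.5 to 100 and their median of -0.14 had been seen before. Whether 1 aberrant library carried the change cannot be told apart from a response of both, since the table gives 1 value per gene and group. An effect of the volatiles stays open and was not tested apart from these.

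The sum of FPKM over chloroplast-encoded genes was 2.92, 2.97 and 1.56 times the control at 3, 24 and 48 h. A few short genes carried much of it: ATCG00080 stood at 278.0 FPKM under the volatiles at 3 h, ATCG00570 at 198.2 at 24 h, and ATCG00630 and ATCG00070 at 102.0 and 48.6 at 48 h, each listed at 0 in controls and all but ATCG00070 untested in the authors' deposited tables, while ATCG00630, tested at 24 h, went from 49.2 to 214.3. Genes under 300 bases held 99.2%, 97.4% and 78.6% of the gain, so very short genes may account for most of it at all 3 times. In longer genes the sums were 87.8 and 89.9 FPKM at 3 h, control first, and the ratios at 24 and 48 h were 1.12 and 1.28, which leaves the rest open. No biological explanation was tested.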
